A study of Mus musculus with 3 samples.

How the data were processed

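Single cells from the subventricular zone of male C57BL/6J mice were sorted into plates and sequenced with SORT-seq, a plate form of CEL-seq in which each well carries a barcode and each transcript a molecular identifier. Per the labels' protocols, 8 mice were used in each of 3 experiments, and the tissue was dissociated with trypsin, enriched on a magnetic column for cells carrying GLAST, the glutamate transporter encoded by Slc1a3, and sorted. Myelin was removed in 2 of the 3 experiments, per the labels' protocols, which do not name them. The 3 samples form 1 group, and each sample is 1 plate. The series design names 3 days and 3 plates, read here as 1 experiment per plate, which no label of a sample states.

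The expression tables hold estimated counts of transcripts, which the authors made from molecular identifiers before they deposited them. The conversion corrects for identifiers that collide by chance. Inverting it gave whole numbers for 100% of the 363716 values above 0, within a tolerance of 1e-06. The submitters' processing notes name BWA 0.7.15, R 4.2.0, Seurat 4.1.1 and the builds hg19 and mm10, without a role for any of them. The gene annotation is not given in the sources used here. The filtered table of 16178 genes and 149 cells equals the unfiltered table of 235 wells in the wells that both hold, so repeating the work from the unfiltered table would give the same values and was not done. The rule by which 86 wells were left out is not given in the sources used here; kept cells have at least 579 genes and the wells left out have at most 421.

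Autofluorescence is an intensity per cell, as deposited, in arbitrary units on a linear scale; the laser, filter and compensation are not given in the sources used here. The deposited count of genes per cell and the deposited total of transcripts were used as they stand. The authors' deposited percent of mitochondrial transcripts equals, in all 149 cells and within 1e-06, the share of 24 listed mitochondrial genes, 2 for ribosomal RNA and 22 for transfer RNA; the 13 protein-coding mitochondrial genes are outside it. The authors' deposited scores for S, G2M and G0 and the authors' phase calls and cluster numbers were used without change, and their gene lists and settings are not given in the sources used here. The plate of a cell was read from the last digit of its library name. In the deposited table per cell, 8 columns were not used here. No doublet caller was run, and doublets stay open.

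Clusters carry numbers only. A cluster was called like a cell type where that type's marker genes, listed before the data were examined, were highest in it with at least 3 of them detected. Transcripts were summed per plate and cluster, or per plate and autofluorescence class, and rounded to whole numbers. These sums, not cells, are the replicates. With plate in the fit, p-values measure the spread of the sums that is left once plate and group are accounted for. Only the alternative without the plate block counts the spread between plates as well. edgeR 4.0.16 in R 4.3.3 was the main tool, with TMM scaling, its filter on low counts, a quasi-likelihood F test, plate as a block and Benjamini-Hochberg adjustment at 0.05. The block was chosen because the cells of a plate are taken to come from 1 experiment. The planned contrast of cells named quiescent against cells named activated could not be made, since no cluster has a name. Clusters were therefore compared by number, as planned for that case, each against the mean of the others.

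A minimum of 10 cells per sum was planned, but cluster 4 never reaches it and cluster 3 reaches it on 1 plate. A minimum of 3 cells was chosen after the cell numbers and before any fit was seen. It gives 11 sums: clusters 1 and 2 on 3 plates, cluster 0 on plates 2 and 3, cluster 3 on plates 1 and 3, and cluster 4 on plate 1 alone, whose lone sum is assumed to vary like the others. The authors made the clusters from the same expression values, so the genes that part clusters describe how they were drawn and are not independent findings.

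Cells above the median autofluorescence of their plate are called high and the others low. The comparison of high with low cells over all clusters was planned. The same comparison made within plate and cluster was planned as an alternative and is treated as a comparison of its own after the data were seen, and so are clusters 0 against 2, the comparison without cluster 1, those in cluster 1 alone and in clusters 0 and 2 alone, the test of the difference between these last, thinned sums, recovered identifier counts and 50 correlations over cells. The planned comparison among quiescent cells was made in cluster 3. Autofluorescence was compared as the difference of median log10 values within each plate, with an exact two-sided sign-flip permutation test over plates, which cannot go below 0.25 with 3 plates or 0.5 with 2.

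For 24 gene lists fixed before the data were examined, camera of limma 3.58.1 was run with a preset correlation of 0.01 on log CPM with a prior count of 2, adjusted over the lists with at least 3 tested genes. Camera with an estimated correlation and fry stand beside it. The text names the 10 genes with the largest fold change in each direction among those eligible. Eligible genes passed the threshold and had a mean of at least 50 CPM over the sums of the comparison. They also had the same sign on every plate with sums of both sides. The text also takes 13 genes fixed beforehand, whatever their values, and up to 4 members with the smallest p of each list described. Of the genes this rule names or the marker lists hold, 5 are not reported here, 1 of them among the 13; they stayed in every fit and count. Any gene outside this rule was chosen after its values were seen. Gene positions are on GRCm38 (mm10) from GENCODE vM21, which matched 311 of 314 named or marker genes and need not be the authors' annotation.

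Alternatives were no replicate block, DESeq2 1.42.0, RLE size factors, no filter on low counts, each plate left out, other minimum cell numbers, 3 cells drawn per cluster and plate, tertiles of autofluorescence, means and ranks. Simulated data with 200 changed genes tested the scripts, with the same mean profile on every plate and 1 dispersion for all genes. They do not give the power in the real data. For high against low cells, 90 of 100 genes changed 4-fold and 100 of 100 changed 16-fold were recovered over 3723 genes, with 6 false calls. For cluster 3 against cluster 4 the numbers were 7 and 65 of 100 over 5329 genes, with 0 false calls. Intervals are exact binomial at 95%, the floor for a count of 0 is 3 counts over the group, and genes with 1 to 3 counts on either side have a ratio of shares of transcripts with its exact interval; all 3 cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest, with 100000 resamples in permutation tests over cells.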

Results

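Single-cell transcriptomes and the autofluorescence of the same cells were measured on 3 plates of GLAST-selected cells from the mouse subventricular zone, the niche of adult neural stem cells. The series title asks whether autofluorescence, light that a cell emits without a label, marks the activation state of neural stem cells. The plates held 63, 79 and 93 wells, of which the filtered table keeps 43, 45 and 61 cells. Their totals were 297573, 413728 and 478504 estimated transcripts, with medians of 4370, 7720 and 7205 per cell and a range from 1208 to 37442. A cell had a median of 2215 genes.

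The 5 clusters of the authors separated oligodendrocyte-lineage-like, microglia-like and stem-cell-like cells. Clusters 0 and 2, with 42 and 35 cells, were oligodendrocyte-lineage-like: Mbp, myelin basic protein, reached 8394 and 6964 CPM (estimated transcripts scaled to a common total) there against 108 in cluster 3. Cluster 1, with 36 cells, was microglia-like and had the highest level of 6 of 6 microglial markers. Its C1qb, a chain of the first complement component, stood at 6462 CPM, Csf1r, the receptor that microglia need to survive, at 5909, and the purine receptor gene P2ry12 at 4022.

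Cluster 3, with 30 cells, was like quiescent neural stem cells or astrocytes, which share most of these markers, and was highest for 9 of 10 of them. Slc1a2, a glutamate transporter, reached 9582 CPM, Clu, which encodes clusterin, 7080, Slc1a3, the selection antigen, 5670, and Aldoc, a glycolytic enzyme of astrocytes and quiescent stem cells, 4741. Cluster 4, with 6 cells, was like activated stem cells or progenitors and was highest for 8 of 8 markers, among them the cyclin gene Ccnd2 at 3622 CPM, Top2a, a topoisomerase of dividing cells, at 2154, and Mki67, a proliferation antigen, at 1384. Egfr stood at 318 in cluster 4 and 57.3 in cluster 3. Cluster 4 was also highest for 4 of the 7 neuroblast markers present, so by the same rule it was neuroblast-like too, though not by the whole list. Among these were Dlx1 and Dlx2, genes of the interneuron lineage, at 686 and 617, while Dcx and Sp9 rested on 3 and 2 transcripts. Cluster 4 had 0 transcripts of Cd24a, Tubb3 and Sp8. Tubb3 and Cd24a were highest in cluster 0, with 26.0 and 1 transcripts. Cluster 1 was also highest for 3 of 5 endothelial or mural markers, at a mean of 47.2 CPM against 3966 for its microglial markers. These genes identify the clusters and are not findings about them.

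**Figure D1:**
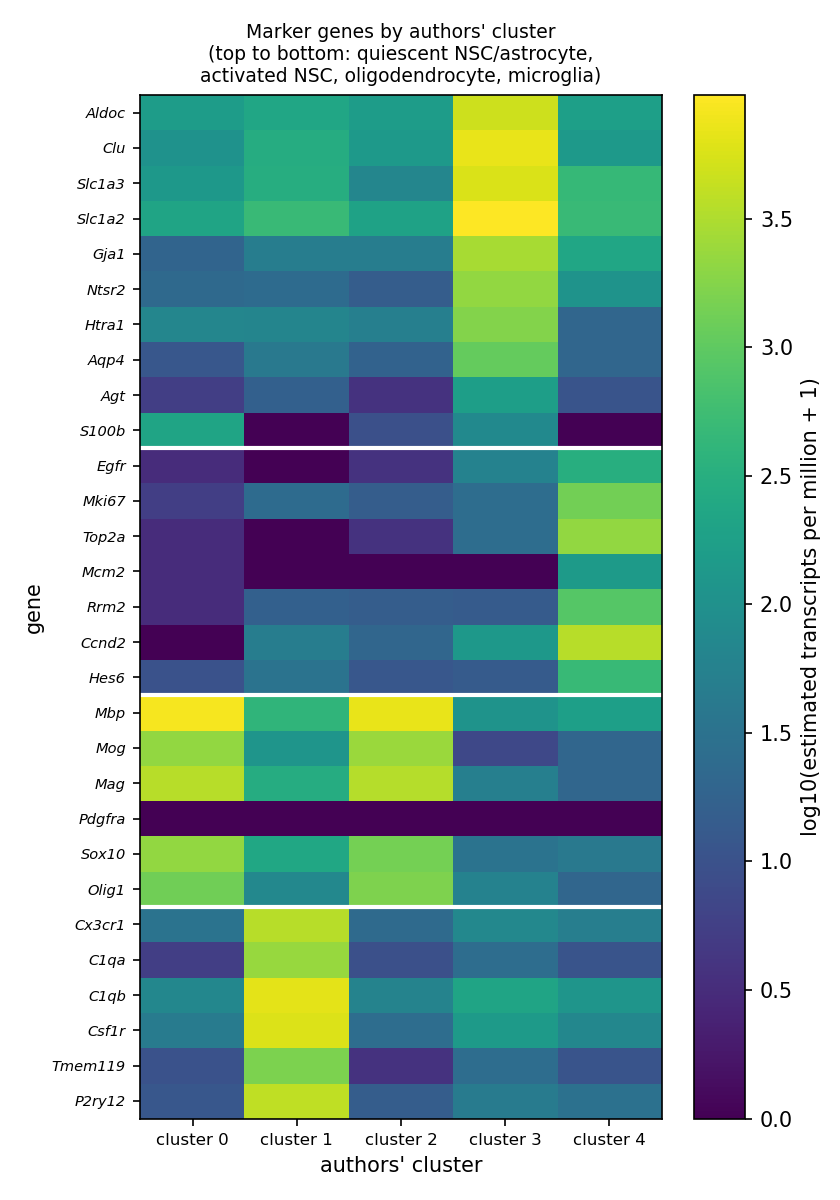
Marker genes in rows and the authors' clusters in columns, coloured by log10 of estimated transcripts in CPM plus 1, pooled over plates. Cluster 3 holds the quiescent and astrocyte markers, cluster 4 the activation markers, clusters 0 and 2 the myelin genes and cluster 1 the microglial genes.

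The makeup of the plates differed. Cluster 3 made up 58.1% of the cells on plate 1 (exact 95% binomial interval 42.1 to 73.0%), 2.22% on plate 2 (0.0562 to 11.8%) and 6.56% on plate 3 (1.82 to 15.9%). Clusters 0 and 2 together made up 9.30% (2.59 to 22.1%), 55.6% (40.0 to 70.4%) and 78.7% (66.3 to 88.1%) of the same plates. Cluster 1 took 20.9%, 40.0% and 14.8%. Cluster 4 had 5 cells on plate 1, 1 on plate 2 and 0 of 61 on plate 3, where the exact interval runs up to 5.87%. As means over 3 plates with their SD, the shares were 26.1 ± 21.1% for cluster 0, 25.2 ± 13.2% for cluster 1, 21.8 ± 14.6% for cluster 2, 22.3 ± 31.1% for cluster 3 and 4.62 ± 6.17% for cluster 4. Each plate is 1 sample, so no test was made between plates, and neither myelin removal nor day can be told apart from them.

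**Figure D2:**
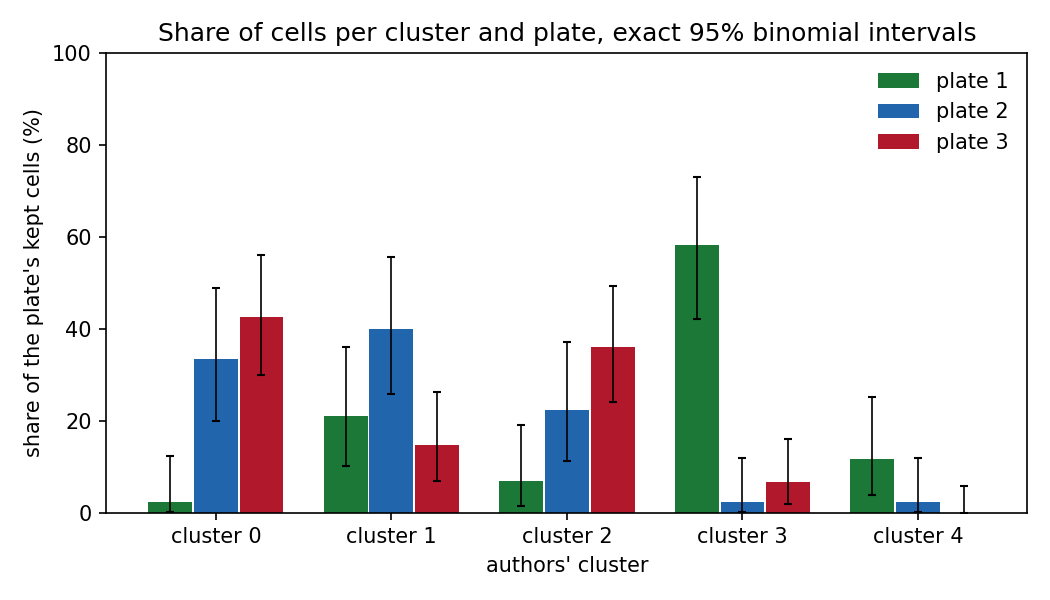
Share of the kept cells of each plate in each of the authors' clusters, in percent, with exact 95% binomial intervals as bars. Cluster 3 is at 58.1% on plate 1 and below 7% on the others.

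The question in the title was addressed by comparing autofluorescence between clusters on the same plate. Of the stem-cell-like clusters, cluster 3 was brighter than cluster 4. It had a median of 1839 units against 1303 in cluster 4 on plate 1 (25 and 5 cells), and 2900 against 787 on plate 2 (1 cell each). Cluster 3 may hold quiescent stem cells, astrocytes or both, which no comparison here parts. The mean ratio over the 2 plates was 2.28-fold (log10 difference 0.358 ± 0.295, SD, n = 2, exact sign-flip permutation p = 0.5, the smallest possible), and on plate 1 alone, with at least 3 cells on both sides, it was 1.41-fold. Cluster 3 was also brighter than the oligodendrocyte-lineage-like clusters 0 and 2, by 1.76-fold (log10 difference 0.244 ± 0.0175, SD, n = 3) and on 3 of 3 plates, though plate 2 holds 1 cell of cluster 3. On the 2 plates with at least 3 cells on both sides it was 1.71-fold, and the cluster 3 cell was the brighter one in a share of pairs of 0.680 on plate 1 and 0.677 on plate 3.

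The brightest cells were microglia-like. Cluster 1 had medians of 4929, 5397 and 3950 units on plates 1 to 3, against 1658, 1577 and 1048 for all other cells. This is 3.37-fold (log10 difference 0.528 ± 0.0519, SD, n = 3), on 3 of 3 plates. Cluster 1 exceeded cluster 3 by 2.23-fold (0.348 ± 0.0793, SD, n = 3) and clusters 0 and 2 by 3.91-fold (0.593 ± 0.0649, SD, n = 3), on 3 of 3 plates each, and cluster 4 by 5.09-fold on 2 plates. Cluster 0 exceeded cluster 2 by 1.27-fold (0.104 ± 0.0690, SD, n = 3). With at least 3 cells on both sides, cluster 1 exceeded cluster 3 by 2.44-fold on 2 plates and cluster 4 by 3.78-fold on 1, and cluster 0 exceeded cluster 2 by 1.33-fold on 2. Each comparison over 3 plates had an exact two-sided sign-flip permutation p of 0.25, the smallest that 3 plates allow.

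**Figure D3:**
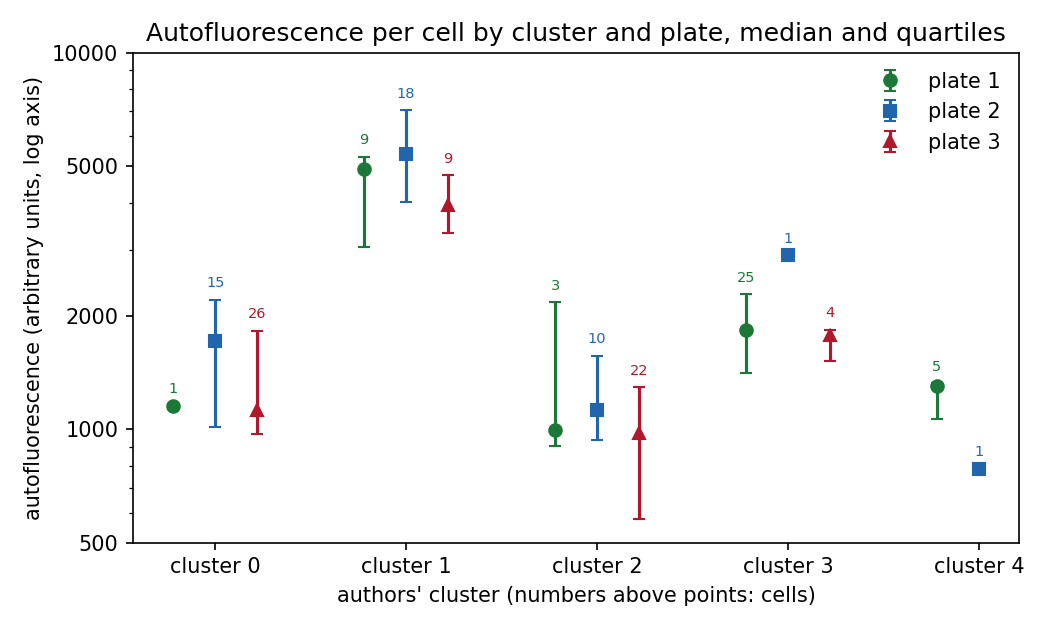
Median autofluorescence per cell in arbitrary units on a log axis, for each of the authors' clusters and each plate, with quartiles as bars and the number of cells above each point. Cluster 1 lies at 4929, 5397 and 3950 units, above every other cluster of its plate.

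The authors' phase calls put 118 cells in G0, 20 in G1, 4 in S and 7 in G2M. Of the cells called G0, 75 belonged to clusters 0 and 2 and 27 to cluster 3. Of the cells called G1, 17 belonged to cluster 1. In cluster 4, 2 cells were called S and 4 G2M. Median autofluorescence was 1594 units in G0, 4623 in G1, 2093 in S and 1064 in G2M, pooled over plates and clusters. Cluster 1 also held 2 of the 4 S cells and 1 of the 7 G2M cells. The S cells of cluster 1 had a median of 5471 units, and those of cluster 4 had 1055. Within cluster 1 the medians were 5019 in G0 and 4929 in G1, and within cluster 3 they were 1839 and 1654. Phase calls alone do not show cycling.

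Genes that went with autofluorescence, whatever the cluster, were asked for by comparing high with low cells of each plate. Of 3723 genes tested, 145 were higher in high cells and 5 lower. The higher ones held 16 of 16 tested microglia genes, 8 of 24 quiescent stem cell genes and 4 of 11 astrocyte genes, lists whose camera calls were lost with an estimated correlation (adjusted p = 0.331, 0.419 and 0.331). Among the largest changes with the same sign on every plate were those of microglial genes: Bin2, at 15:100641077-100669553, rose by 4.51 on the log2 scale (SE 0.59, edgeR adjusted p = 4.7e-05), from 6.48 ± 2.52 to 167 ± 82.9 CPM (SD, n = 3). Itgb5, an integrin subunit, rose by 4.25, C1qa, a complement chain at 4:136895917-136898803, by 4.14 (SE 0.43), the lectin gene Siglech by 4.12, the phosphatase gene Inpp5d by 3.94, Abi3 and the Fc receptor-like gene Fcrls by 3.72 each, the phospholipase D family gene Pld4 by 3.71, and Ctss, a lysosomal protease of microglia, by 3.67 (SE 0.37). Low cells had more Ccnd2 (log2 -3.98, SE 0.71, lower on 2 of 3 plates), Mphosph8, a chromatin silencing gene (-2.25), Il33, an alarmin (-1.93), Hsph1, a heat shock gene (-1.86), and Nsmce4a, a DNA repair gene (-1.73), the last 4 on 3 of 3 plates.

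All 16 tested microglia genes rose, with a median of 3.41, and 16 did when adjusted over the list alone; C1qc rose by 3.56 and C1qb by 3.26. High cells held 32 of the 36 cells of cluster 1, which gave 21.5 ± 11.5% of their transcripts against 1.78 ± 2.31% in low cells (SD, n = 3), and 116 of the 145 higher genes were also higher in cluster 1 than in the mean of the other clusters (80.0%, against 9.04% of all genes tested in both). Of 55 lysosome genes, 10 rose, 0 fell and 45 did not pass, 13 adjusted over the list alone. Among them Laptm5 rose by 3.32 and Ctsd, the protease cathepsin D, by 2.84. The general lysosomal genes Lamp1 and Psap had values of 0.18 (adjusted p = 0.908) and 0.80 (0.326), and Ctsb 1.15 (0.0887).

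Of 24 quiescent stem cell genes, 8 rose and 16 did not pass, 13 rising adjusted over the list alone: Fgfr3, a growth factor receptor, by 2.02, Sparcl1 by 1.76, the gap junction gene Gja1 by 1.59 and Clu by 1.47. Of 11 astrocyte genes 4 rose, 7 over the list alone, with Aqp4, a water channel, at 2.30 and Bcan, a matrix proteoglycan, at 1.94. Cluster 3 gave 63.9% of the transcripts of high and 29.5% of those of low cells on plate 1, and 7.81% and 1.23% on plate 3; on plate 2 it gave 2.06% in high cells and had no cell among the low ones. Slc1a3 rose by 1.20 and Ptprc, the pan-leukocyte antigen, by 2.32, which are the 2 of 4 sort markers past the threshold. Aldoc had 0.85 (adjusted p = 0.375). Of 11 genes of the response to dissociation 5 rose, 8 over the list alone, among them the immediate early genes Junb by 2.49, Egr1 by 2.14 and Fos by 1.73. Olig2 in the activated list had -0.92 (adjusted p = 0.23).

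Camera with its preset correlation called 12 of 19 lists. Microglia (adjusted p = 9.0e-36, median 3.41), quiescent stem cell (2.2e-09, 0.92), dissociation (3.1e-09, 1.57), lysosome (9.5e-08, 0.44), astrocyte (1.2e-07, 0.97) and sort markers (0.0171, 0.80) were called up. Ribosomal protein (0.000329, -0.34), chaperone (0.000676, -0.40), proteasome (0.00289, -0.38), G2M (0.00683, -0.61), S phase (0.0111, -1.01) and oxidative phosphorylation genes (0.0171, -0.23) were called down, with 1 of their members, Hsph1, past the threshold. With an estimated correlation the adjusted p was 0.331 for microglia, astrocyte and dissociation, 0.419 for the quiescent, lysosome, S phase and sort marker lists, 0.449 for proteasome, chaperone and oxidative phosphorylation, 0.569 for G2M and 0.743 for ribosomal protein. Without plate 1, which holds 5 of the 6 cells of cluster 4, 6 lists were called: the lists called down lost their call, with medians of 0.05 for G2M and 0.15 for ribosomal protein genes. The activated stem cell (median -0.86, 1 up and 1 down), neuroblast (-0.34), autophagy (-0.10, mean 0.05), glycolysis (0.13), fatty acid oxidation (0.03), oligodendrocyte (-0.11) and oligodendrocyte precursor lists (-0.46, mean 0.15) were not called.

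Several activation genes did not pass the filter on low counts. Their summed transcripts in high and low cells were 0 and 223 for Top2a, 6 and 148 for Mki67, 5 and 66 for Dlx2, 5 and 38 for Egfr and 0 and 3 for Dcx. No cell of cluster 4 was among the high cells. Without the plate block edgeR called 0 genes (207 at an unadjusted p under 0.05), DESeq2 with the block called 95, and without plate 2 the count was 39.

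**Figure D4:**
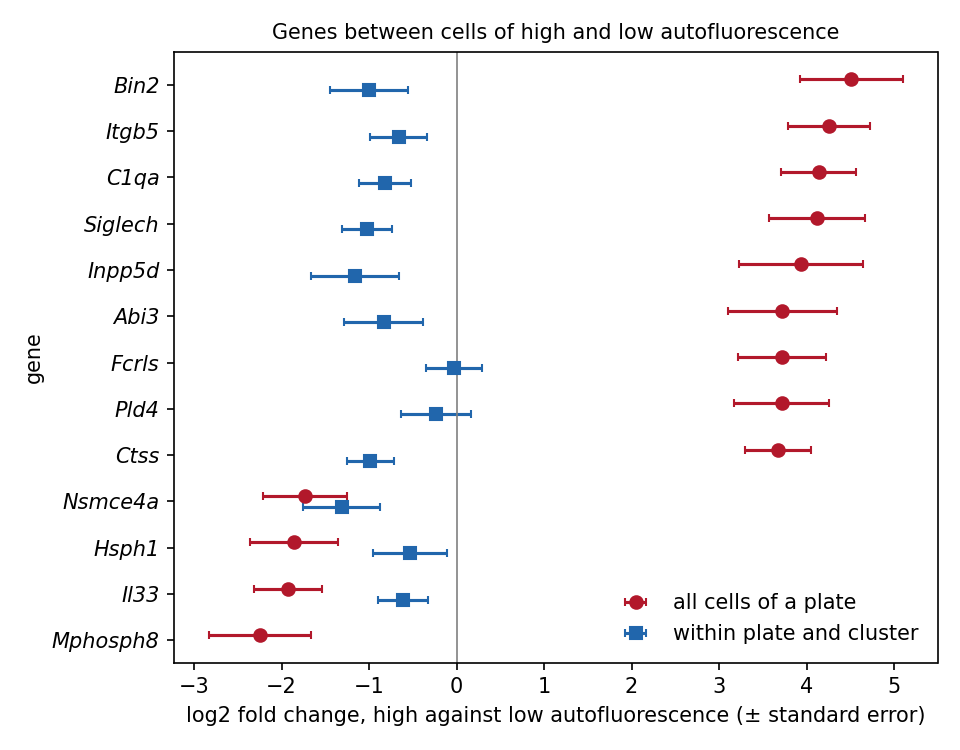
Log2 fold change with its standard error of genes with large changes between high and low cells (circles), and of the same genes when high and low cells were taken within plate and cluster (squares). The microglial genes lie between 3.67 and 4.51 over all cells and below 0 within clusters, where the filter on low counts left out Mphosph8.

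To set nearly equal numbers of cells of each cluster on both sides, high and low cells were also taken within plate and cluster. Of 3412 genes tested, 0 were then higher and 3 lower, and the 3 were microglial: P2ry12, at 3:59216272-59262871, had a log2 change of -1.55 (SE 0.28, edgeR adjusted p = 0.00442), its neighbour P2ry13, at 3:59207892-59210882, -1.49 (SE 0.33, 0.038) and Csf1r, at 18:61100598-61132149, -1.13 (SE 0.25, 0.038), each lower on 3 of 3 plates. P2ry12 and P2ry13 encode purine receptors of resting microglia. The 3 genes went from 731 to 268, 273 to 90.9 and 1027 to 486 CPM. The mix of transcripts was not made equal: cluster 1 gave 8.70 ± 6.27% of the transcripts of these high cells and 14.7 ± 7.02% of the low cells (SD, n = 3).

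Of 17 microglia genes 2 fell, 14 adjusted over the list alone, and their median was -0.99 (camera adjusted p = 2.8e-15; adjusted p = 0.839 with an estimated correlation). The oligodendrocyte list had a median of 0.58 with 5 of 14 rising over the list alone and 0 over all genes (4.2e-07; adjusted p = 0.896 with an estimated correlation). Cluster 2 gave 11.9%, 43.3% and 45.7% of the transcripts of these high cells on plates 1 to 3, against 5.44%, 22.5% and 33.8% of the low cells. In clusters 0 and 2 alone this list had a median of 0.43 (camera adjusted p = 0.0200; 0.935 with an estimated correlation), with 0 of 14 genes past the threshold. Dissociation genes had -0.47 (0.00258; 0.839 as the adjusted p with an estimated correlation) and ribosomal protein genes -0.17 (0.00279; 0.896). The lysosome list had -0.15 with 0 of 54 past the threshold, and the quiescent stem cell list 0.25 with 0 of 21. In cluster 3, like quiescent stem cells or astrocytes, edgeR called 0 of 437 genes on 2 plates (7 at an unadjusted p under 0.05). Its 4 sums held 12 high and 13 low cells on plate 1 and 2 of each on plate 3. They left 1 residual degree of freedom, so this count of 0 does not show that no gene changed. In cluster 3 DESeq2 called 0 as well (4 unadjusted). DESeq2 also called 0 genes within clusters (62 unadjusted), no block gave 0 (40 unadjusted), RLE size factors gave 4 higher and 16 lower, and the count was 23 without plate 1, 2 without plate 2 and 0 without plate 3 (201 unadjusted).

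Without the microglia-like cluster, 10 genes of 2913 were higher and 1 was lower in high cells. Of these, 11 of the 11 were also past the threshold over all cells, where 150 of 3723 genes were. That comparison holds the same cells, so the overlap is no separate support. Among the higher genes were Slc4a4, a bicarbonate transporter (log2 2.73), Aqp4 (2.63), F3, tissue factor (2.58), Fgfr3 (2.45), Bcan (2.35), Vegfa (2.28), Sparcl1 (2.12), Gpm6a (2.03) and Clu (1.69), each higher on 3 of 3 plates. Ccnd2 had -4.98, lower on 2 of 3 plates. Of 22 quiescent stem cell genes 3 rose, 16 adjusted over the list alone, and of 11 astrocyte genes 2 did, 7 over the list alone. Camera with its preset correlation called 9 of 16 lists. Quiescent stem cell (adjusted p = 1.2e-14, median 1.16), astrocyte (1.4e-09, 1.34), lysosome (0.0226, 0.21) and fatty acid oxidation genes (0.0320, 0.20) were called up. Ribosomal protein (1.4e-18, -0.73), chaperone (0.000157, -0.30), activated stem cell (0.000587, -0.74), proteasome (0.0208, -0.36) and G2M genes (0.0274, -0.50) were called down. With an estimated correlation the adjusted p of these 9 was 0.481 for lysosome, 0.439 for proteasome and 0.407 for each other list. Of 67 ribosomal protein and 45 lysosome genes edgeR called 0, and 0 adjusted over the list alone. Ctsd stood at 0.81 (edgeR adjusted p = 0.753) and Slc1a3 at 1.21 (0.282). The mix of clusters was not made equal here, and all cells of cluster 4 were low. They reached at most 1581 units on plate 1, where cells outside cluster 1 had a median of 1658. On plate 2 the values were 787 and 1577. Summed transcripts in high and low cells were 1 and 222 for Top2a and 3 and 148 for Mki67. Whether the genes and lists called here go with autofluorescence or with the mix of clusters cannot be told from this comparison.

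Cluster 3, like quiescent stem cells or astrocytes, was set against cluster 4, like activated stem cells or progenitors. Cluster 3 had more of most quiescent and astrocyte genes tested, and cluster 4 more of most G2M and ribosomal protein genes. The comparison rests on 2 sums of cluster 3 and 1 sum of 5 cells of cluster 4, and the clusters were drawn from the same values. Only plate 1 holds sums of both clusters, so the rule of the same sign was checked on that plate alone. Of 5329 genes, 181 were higher and 312 lower in cluster 3. With RLE size factors, which moved the median of all genes by 0.23, these were 353 and 356, and with DESeq2 205 and 180.

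The 10 leading higher genes had 0 transcripts in cluster 4, and the fold of each is given as a lower bound over a floor of 3 counts in the group. Id2, a repressor of differentiation factors, was at least 26.1-fold higher; the bounds were 19.4 for Cyp2d22, 17.0 for Nkain4, 16.8 for Syne1 and Prex2, 15.8 for Gabrb1, a GABA receptor subunit gene, 14.4 for the connexin gene Gjb6 and the zinc transporter gene Slc39a12, 12.02 for Gabrg1 and 11.8 for the GABA transporter gene Slc6a11. The 10 leading lower genes had 0 transcripts in cluster 3. The cyclin gene Ccna2 was at least 53.8-fold lower; the bounds were 32.2 for Ckap2l and Racgap1, of the spindle and cytokinesis, 26.6 for the condensin gene Smc2, 24.9 for Cdca8 and Ezh2, a histone methyltransferase gene, 21.6 for Rrm1, of ribonucleotide reductase, 20.5 for Trim59, 18.3 for Insm1 and 17.2 for the mitotic transcription factor gene Foxm1.

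Of 30 quiescent stem cell genes 20 were higher and 10 did not pass, with Sparcl1 at 5.55, Clu at 5.50 (SE 0.75), Aldoc at 4.40 (SE 0.73) and Slc1a2 at 4.03. Of 19 astrocyte genes 12 were higher, led by Bcan, at a ratio of 190.0 (exact 95% counting interval 33.9 to 7528), and Fam107a, at 141 (25.01 to 5580), each from 1 count in cluster 4. Of 20 activated stem cell genes 12 were lower, among them Ccnd2 at -4.63 and Ptma at -3.35. Hmgb2 was lower by a ratio of 119.8 (interval 32.6 to 998) from 2 counts in cluster 3. Of 45 G2M genes 29 were lower, with Top2a at -6.18 (SE 0.99) and Mki67 at -5.60, and of 23 S phase genes 7, with Pcna at -4.13 and Rrm2 lower by a ratio of 64.9 (interval 17.4 to 545) from 2 counts. Among 9 neuroblast genes 3 were lower, Stmn1 at -4.78, Dlx2 at -4.41 and Dlx1, by a ratio of 83.2 (14.3 to 3350) from 1 count. Egfr had -2.48 (adjusted p = 0.206).

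Of 69 ribosomal protein genes 56 were lower, with a median of -2.49 and Rpl12 at -4.08, and 9 of 30 chaperone genes, such as Hsp90aa1 at -2.85. Of 65 lysosome genes 6 were higher and 59 did not pass, 8 over the list alone: Ctsb stood at 3.33 (SE 0.76), Ctsd at 2.77, Psap at 2.33, Lamp1 at 1.72 (adjusted p = 0.0574), and Ctsl and Ctsa at least 9.02-fold and 6.21-fold higher. Among 19 fatty acid oxidation genes 3 were higher, with Acsl3 at 2.92, Acsl6 at 4.097 and the carnitine transferase gene Cpt1a at least 6.41-fold higher, and 3 of 17 glycolysis genes, Aldoc, Aldoa at 2.49 and Slc2a1 at least 5.01-fold. Slc1a3 stood at 3.32.

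Camera called the quiescent, G2M and S phase lists with an estimated correlation too (adjusted p = 0.0228 each). The lists called with the preset correlation alone had, as adjusted p with an estimated correlation, 0.0676 (astrocyte), 0.0739 (activated stem cell), 0.0742 (neuroblast), 0.341 (ribosomal protein), 0.645 (oxidative phosphorylation, median -0.75) and 0.459 (lysosome, chaperone, glycolysis, fatty acid oxidation, proteasome, oligodendrocyte and endothelial). The autophagy (0.46), dissociation (0.13), oligodendrocyte precursor (0.83), microglia (0.58) and sort marker (0.86) lists were not called; these are medians on the log2 scale under TMM. With genes at 0 counts on either side set to their bound, or to 0 without one, the dissociation and sort marker medians were 0 and 0.70. Among the lists called, the oligodendrocyte median went from 2.85 to 0.32 (7 of 14 genes at 0 on 1 side), endothelial from 3.67 to 0.47 (5 of 8), lysosome from 1.45 to 1.00 (11 of 65), quiescent from 3.65 to 3.30, astrocyte from 4.30 to 3.85, activated stem cell from -4.27 to -3.15, S phase from -4.21 to -3.80, G2M from -5.41 to -4.24 and chaperone from -2.10 to -1.92. The others stayed.

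The 2 oligodendrocyte-lineage-like clusters were close to each other, with 7 genes higher and 2 lower in cluster 0 of 5329 tested. Cluster 0 had more Pmp22, a myelin protein gene (ratio 82.0, exact 95% counting interval 14.4 to 3270, from 1 count in cluster 2), Enpp6, a marker of newly forming oligodendrocytes (58.5, 10.2 to 2345, 1 count), and S100b (26.2, 8.70 to 129, 3 counts). It also had more Slco3a1 (log2 4.41), the selenoprotein gene Sepp1 (3.93), Gng11 (3.13) and Serpinb1a (2.85). Cluster 2 had more Cntn1, a contactin (-3.82), and Ptgds, a prostaglandin synthase of mature oligodendrocytes (-1.55). Each had the same sign on 2 of 2 plates, and edgeR adjusted p ran from 4.5e-11 for Sepp1 to 0.0371 for Ptgds. None of the 20 lists was called, and the smallest camera adjusted p was 0.126, for oligodendrocyte genes with a median of -0.25. With at least 10 cells per sum, 34 genes were higher and 40 lower, and the count was 26, 1 and 1 without plates 1, 2 and 3.

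Against the mean of the other clusters, 386 genes were higher and 52 lower in cluster 0, 643 and 368 in cluster 1, 444 and 101 in cluster 2, 396 and 102 in cluster 3, and 343 and 88 in cluster 4. The counts of cluster 4 rest on 1 sum, which is assumed to vary like the others. Leading genes by fold were Slco3a1 and Serpinb1a in cluster 0, Siglech in cluster 1, Cntn1 and Crtac1 in cluster 2, Bcan in cluster 3, and Top2a and Ccna2 in cluster 4. With RLE size factors the splits were 443 and 106 for cluster 0 and 382 and 195 for cluster 4.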

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

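Tests chosen after the results were seen were those of plates as the source of bright cluster 1 cells, of the share of cluster 1 transcripts, first set on the median of the microglia list and changed to the 3 genes once that median was seen to go with the explanation, and of the comparisons in cluster 1 alone and in clusters 0 and 2 alone; thinning was added after the data but before its result was seen.

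A difference between groups appeared in how transcript number went with autofluorescence inside clusters. In cluster 1 the high cells had fewer estimated transcripts than the low cells on 3 of 3 plates (mean log10 ratio of medians -0.136 ± 0.0587, SD, n = 3), and in cluster 2 they had more on 3 of 3 (0.399 ± 0.236, SD, n = 3), a gap of 0.535. In cluster 3 the high cells had more on 2 of 2 plates (0.205 ± 0.0196, SD, n = 2), a gap of 0.341 to cluster 1. Neither gap was tested. Plate 1 of cluster 2 had 1 high and 2 low cells, and without it the mean was 0.263. Cluster 0 had 0.0276 ± 0.0521 (SD, n = 2), with more in high cells on 1 of 2 plates. Over the single cells of cluster 1 the rank correlation was 0.0333, 0.00516 and -0.383 on plates 1 to 3, above 0 on 2 of 3, so the lower medians of its high cells are not borne out cell by cell.

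The 86 wells left out of the filtered table, which no comparison uses, held cell type transcripts above the floor of 3 counts. There were 568 estimated transcripts of Mbp, 63.0 of the astrocyte and stem cell gene Slc1a2, 23.0 of the microglial gene C1qb and 4 of the endothelial gene Cldn5, among 28702 transcripts of all genes. Mbp was in 60 of these wells.

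The genes higher in autofluorescent cells were mostly those of cluster 1. Chance allotment of cells was argued against: in 100 redraws of high and low cells within plate, 0 gave as many as 150 genes, and the highest gave 5. Lower depth of the high cells as the whole cause was also argued against: with every sum thinned to the lowest total 107 genes passed, among them 98 of the 150, of which 106 could still be tested. The mix of clusters is a candidate explanation: when cells were redrawn within plate and cluster, which keeps that mix, 53 of 100 redraws gave at least as many genes, with a mean of 157 and a highest count of 233. The 6 sums allow 10 splits, too few for a share under 0.05; 1, the real one with 150 genes, reached that count and the highest other gave 0.

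Cluster 1 cells were the brightest. The difference was measured within plates and held on 3 of 3, which a difference between plates alone cannot give; this is the reported value itself and no further test. Its lower depth, with a median of 3455 transcripts per cell, was argued against by cells of other clusters of like depth: the cluster 1 cell was the brighter one in a share of pairs of 0.874 on plate 1 (15 other cells), 0.907 on plate 2 (3 cells) and 1 on plate 3 (3 cells). No biological explanation was tested, and doublets were not examined.

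Within clusters, P2ry12, P2ry13 and Csf1r were lower in high cells. A lower share of cluster 1 transcripts among these high cells could account for part of it: in cluster 1 alone the 15 microglia genes tested had a median of -0.12, against -0.99 over 17 genes in all clusters, and Csf1r went to -0.24 (SE 0.29). P2ry12, the median of the 3 genes, stood at -0.70 (SE 0.32, edgeR adjusted p = 0.999) and P2ry13 at -0.84 (SE 0.46, 0.999), between 0 and their values over all clusters, so a real change in microglia-like cells and the altered mix cannot be told apart for these genes. The 10 splits are too few for a share under 0.05. The real split gave 3 genes, 3 splits gave as many, and the highest other gave 5. The splits with 5 genes part high from low cells on plate 1 only and are the same fit once plate is in the model. The other splits that part them on 3 of 3 plates gave 0. In cluster 1 alone edgeR called 0 of 210 genes (2 at an unadjusted p under 0.05), in clusters 0 and 2 alone 0 of 2507 (52), and in the test of the difference between these 0 of 623 (17); no other tool was run on them.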

How the results depend on the processing

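The comparison without cluster 1, those in cluster 1 alone and in clusters 0 and 2 alone, the count with the middle cell left out, sums of at least 1 cell, recovered identifier counts, thinned sums, and shares and autofluorescence on fewer plates were chosen after the data were seen. All 42 alternative values of the 7 autofluorescence differences kept their direction, though none of these could pass a test. Those on fewer plates could not reverse, since each difference had the same sign on every plate. All 23 alternative values of the 6 mean shares stayed within 1 SD. Those with a plate left out could not move by more than that. Only the shares over cells with at least 2 times the lowest total of transcripts could have failed. Of 100 alternative counts of genes, 51 stayed within 1.5 times the count reported, and of 20 counts of lists 11 did. Among named genes past the threshold, 229 of 356 alternative values for all cells, 11 of 33 within clusters, 487 of 536 for cluster 3 against cluster 4 and 58 of 87 for cluster 0 against cluster 2 kept direction and call; 19 reversed, all of them over all cells.

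Counts against the mean of the other clusters moved without the replicate block to 971 (cluster 0), 865 (cluster 2) and 1019 (cluster 4) genes. Drawing 3 cells per cluster and plate gave 157, 281, 238, 162 and 133 genes for clusters 0 to 4, 121 for cluster 3 against cluster 4 and 1 for cluster 0 against cluster 2, from 1094 genes tested. No filter gave 176 for cluster 4 and 258 for cluster 3 against cluster 4, and sums of at least 1 cell gave 596 for cluster 1. With 1 plate left out, the counts ran from 111 to 794 for cluster 0, 385 to 898 for cluster 1, 240 to 720 for cluster 2, 179 to 374 for cluster 3, 143 to 172 for cluster 4 and 214 to 217 for cluster 3 against cluster 4. Cluster 0 against cluster 2 had 9 genes, 14 without the replicate block, 2 with DESeq2 (138 unadjusted), 74 with at least 10 cells per sum, 3 with sums of at least 1 cell, and 1 to 26 with a plate left out. The cause was not tested, but fewer genes were tested with drawn cells, sums of at least 1 cell or a plate left out, and more with no filter. Without plate 1, cluster 4 had no sum, so the mean of the other clusters left it out there.

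For high against low cells over all clusters, 150 genes became 0 without the replicate block (207 unadjusted), 95 with DESeq2, 307 with no filter, 98 between the outer tertiles, 3 within plate and cluster, 11 without cluster 1, and 39 to 180 with a plate left out. DESeq2 shared 85 of the 150, and 128, 39 and 98 stayed without plates 1, 2 and 3. Within clusters, 3 genes became 0 without the replicate block (40 unadjusted), 0 with DESeq2 (62), 20 with RLE size factors, 0 between tertiles (110), 0 in cluster 1 alone (2), 0 in clusters 0 and 2 alone (52), 1 with the middle cell left out, and 0 to 23 with a plate left out. Lists called over all cells went from 12 to 0 with an estimated correlation and 0 with fry, and to 6 to 13 with a plate left out; within clusters from 4 to 0, 0 and 2 to 7; for cluster 3 against cluster 4 from 15 to 3 and 7. The cause was not tested.

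Over all cells, the microglial and immediate early genes reversed once high and low cells were taken within plate and cluster, which evens the number of cells per cluster but not their transcripts, of which cluster 1 gave 8.70% in high and 14.7% in low cells: Bin2 -1.003, Itgb5 -0.66, C1qa -0.81, Siglech -1.02, Inpp5d -1.16, Abi3 -0.83, Fcrls -0.028, Pld4 -0.24, Ctss -0.99, Ctsd -0.22, Fos -1.14, Laptm5 -0.76, Junb -0.63, Egr1 -1.09, Zfp36 -0.57, C1qc -0.86, C1qb -0.72 and Ptprc -1.36, none past the threshold (edgeR adjusted p from 0.0825 to 1.00). C1qb reversed to -0.063 without cluster 1 as well. The ribosomal protein list reversed from -0.34 to a median of 0.15 without plate 1 (camera adjusted p = 0.332), in a range from -0.64 to 0.15 with a plate left out; the cause was not tested.

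Depth limits the sparse genes: the filter left 437 genes for cluster 3 and 210 for cluster 1 alone. In cluster 3 alone, 0 genes stayed 0 without the replicate block (10 unadjusted), with DESeq2 (4), RLE size factors (10), no filter (43), recovered identifier counts (7) and tertiles (1). Each of these fits rests on 4 sums, so the counts of 0 say little on whether genes change. A minimum of 20 cells per sum, one of 10 for clusters against the mean of the others and for cluster 3 against cluster 4, a fit of clusters 3 and 4 alone, contrasts with cluster 4 without plate 1, and cluster 3 alone without plate 1 or 3 could not be fitted.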

Other observations

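Tests in this part were chosen after the results were seen, except those of the G1 calls and of swapped cluster names.

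The deposited percent of mitochondrial transcripts covers a small part of them. It has a median of 2.23% over 149 cells, and all 37 mitochondrial genes together 11.5%, because the 13 protein-coding genes alone reach 9.30%. The microglia-like cluster 1 had the lowest median with all 37 genes, 7.08%, against 11.7% in cluster 0, 13.1% in cluster 2, 11.9% in cluster 3 and 12.6% in cluster 4. In the 86 wells left out it was 25.9%.

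Autofluorescence went with the number of transcripts over cells of clusters 0, 2 and 3. Over the 5 sets of these cells on 1 plate with at least 6 cells, 98 cells in all, the mean rank correlation was 0.491, above 0 in 5 of 5 sets (one-sided permutation p = 2.0e-05). These clusters and the direction were chosen after results of the same cells were seen, so this p is not independent support. The rank correlation was lowest in cluster 0, 0.246 on plate 2 and 0.359 on plate 3, and cluster 4 was not included. In cluster 1 it was -0.115 over 3 sets and 36 cells, above 0 in 2 of 3 sets (p = 0.725, permutation). The strongest single relation was cluster 2 on plate 3 with 22 cells: Pearson r = 0.809 (permutation p = 1.0e-05, the smallest that 100000 permutations can give, adjusted 0.00025) and Spearman rho = 0.792 (permutation p = 2.0e-05, adjusted 0.001), with r = 0.742 without the 2 farthest cells. Of 50 relations, 2 passed the threshold; the other, clusters 0 and 2 on plate 3, holds the same cells. Cells are not replicates of the experiment. Cell size and doublets were not measured, so the cause stays open.

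The authors' G1 calls lay mostly in cluster 1, where 47.2% of cells had them (exact 95% binomial interval 30.4 to 64.5%). Among 12 cells of other clusters with no more transcripts than the median of cluster 1, 8.33% did (0.211 to 38.5%), and among the 18 cells of cluster 1 of that depth 38.9% (17.3 to 64.3%). Among the 101 deeper cells of other clusters 1.98% did (0.241 to 6.97%). The intervals of the shallower cells overlap with each other and with that of all of cluster 1. Low depth could therefore account for these calls or not.

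For the genes that part cluster 1 from the mean of the other clusters, 1 of 100 arrangements of cluster names among the sums of a plate, the real one, gave as many as 1011, and the highest other gave 905. For cluster 2, 3 of 100 gave as many as 545, and the highest other gave 845. The clusters were drawn from the same values, so this says nothing on chance for either count. Without cluster 1, high against low cells gave 11 genes; 3 of the 10 splits gave as many, the highest other gave 373, and 10 splits are too few for a share under 0.05. The splits with 373 part high from low cells on plate 1 only and are the same fit once plate is in the model. Plate 1 holds 25 of the 30 cells of cluster 3 and 5 of the 6 of cluster 4. Whether this gives the 373 genes was not tested. Among the splits that part high from low cells on all 3 plates, the others gave 0.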
